A study of Mus musculus with 12 samples.

How the data were processed

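RNA sequencing of mouse lung was measured in 12 libraries, 3 in each of 4 groups. All mice carried loxP sites in both copies of Slc39a1, which encodes the zinc importer ZIP1. In 2 of the groups the labels add a CreERT2 driver, a recombinase fused to a modified oestrogen receptor and switched on by tamoxifen, aimed at alveolar type 2 (AT2) cells. The labels give total RNA, a TruSeq library kit and a NovaSeq sequencer. They name lung as the tissue and AT2 as the cell line, while the series text speaks of lung tissue, so the libraries were read as lung and not as sorted cells.

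Groups were set from the titles, the genotype tags and the headers of the deposited comparison tables. They are named here floxed vehicle (replicates 21, 22 and 23), Cre vehicle (10, 17 and 19), floxed LPS (3, 5 and 6) and Cre LPS (1, 3 and 4). LPS is bacterial endotoxin. The treatment tag gave vehicle for every floxed library and LPS at 1 day for every Cre library, which contradicts the 4 sets in the series text. The table headers place the floxed LPS and Cre LPS libraries among the LPS-treated ones, and that grouping was used. The title of Cre vehicle replicate 19 has 1 letter more than its group's other titles, and it was placed by its genotype tag and table header.

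The deposited matrix holds estimated (expected) read counts per gene, not normalised, and 10.9 to 12.9% of the values of a library are not whole numbers. The counting tool, the aligner and the annotation were not stated. The deposited notes name the build GRCm39 and DESeq2, without a version. In the authors' 2 comparison tables, which list only genes passing their thresholds, the deposited columns give the same expected counts, TPM, a log2 fold change and an adjusted p-value. Every listed gene there has a log2 fold change of at least 1 in size and an adjusted p under 0.05. The reference annotation at hand was made for another build, so no coordinates are given; it supplied gene type and transcript GC content (98.2% of tested genes had one), while gene lengths came from the deposited file.

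Of 57893 features in the matrix, 913 loci without a gene name were left out of the comparisons and counted apart; they held 0.415 to 0.932% of the counts of a library. Totals ran from 18938250 to 25935098 counts per library. Counts were rounded and filtered with edgeR's filterByExpr (minimum count 10), which kept 17500 genes. Libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model in edgeR 4.0.16 under R 4.3.3 gave 1 mean per group to all 12 libraries, and 6 contrasts were tested: genotype with vehicle, genotype with LPS, LPS in floxed mice, LPS in Cre mice, their interaction, and genotype averaged over vehicle and LPS. Benjamini-Hochberg adjustment covered all tested genes of a contrast, with a threshold of 0.05. Values are given as CPM, counts scaled to the normalised library size, with the SD of 3 libraries, and log2 fold changes with their SE. These p-values measure spread between samples. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so no such test is given.

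Before the data were examined, the design, 45 gene lists and a rule for named genes were fixed. The rule took Slc39a1 and, per contrast, up to 10 protein-coding genes in each direction with the largest fold change among those with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the libraries of the groups. Chance alone gives no overlap to 10% of genes with 3 libraries against 3. Lists with at least 3 tested members were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and again with a correlation estimated per list, and with the rotation test fry. Members were counted as called over all tested genes and also when adjusted over the list alone. Terms of the deposited gene annotation with 10 to 500 tested genes were tested by a one-sided hypergeometric test against the 16515 tested genes that carry any term, with Benjamini-Hochberg adjustment over 3406 terms. Where a gene had 0 counts in a group, its fold is a lower bound against a floor of 3 counts summed over the 3 libraries; with 1 to 3 counts the ratio is given with a 95% counting interval. Such intervals and floors cover counting error only.

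Alternatives were DESeq2 size factors in edgeR, library totals without TMM, no filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, only the 6 libraries compared, each library left out in turn, a log2 fold change of at least 1, and a covariate for sex. Sex was read from Xist and 4 Y-linked genes and differed within only 1 group, floxed LPS, so the covariate rests on 1 male-pattern library against 2 female-pattern libraries. After the data were seen, 3 alternatives were added. They were a smooth trend on gene length and GC content taken out of each library, the 2 female-pattern floxed LPS libraries left out, and the sex covariate in DESeq2 and limma-voom. Figures were drawn with matplotlib 3.10.9.

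The procedure was tested on simulated data with the depth and spread of these libraries. With vehicle libraries edgeR recovered 7.46% of genes changed by a fold of 1.5, 61.2% of those changed by a fold of 2 and 95.5% of those changed by a fold of 4, with 7 false calls among 17177 genes. With LPS libraries it recovered 13.4, 61.2 and 97% of these classes, with 8 false calls among 17203 genes. DESeq2 recovered 82.1 and 83.6% at a fold of 2, with 40 and 50 false calls. A length slope of -0.35, that of the vehicle comparison, put on simulated Cre vehicle libraries with no changed genes gave 1251 calls before and 0 after the length and GC correction, and a slope of -0.20 gave 2 and 0. In the simulated LPS comparison, where no trend was put in, the correction kept 100% of the true calls in both runs. This does not show how many true calls it would keep in a comparison with a trend.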

Results

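The data set holds RNA-seq counts from the lungs of mice with loxP-flanked Slc39a1, with or without an inducible AT2-cell Cre, given vehicle or LPS, with 3 libraries per group. Floxed vehicle libraries held 20364924 to 23692712 counts, Cre vehicle libraries 18938250 to 20177431, floxed LPS libraries 19602470 to 24316158 and Cre LPS libraries 19704039 to 25935098. All 18 AT2 markers, 14 fibroblast markers and 16 capillary endothelium markers passed the expression filter. Sftpc, the AT2 surfactant gene, stood at 13090 ± 1430 CPM in floxed vehicle (SD, n = 3), 12080 ± 1940 in Cre vehicle, 3348 ± 2180 in floxed LPS and 1719 ± 496 CPM in Cre LPS lungs. The first principal component held 53.2% of the variance and parted vehicle from LPS libraries. The second held 21.6% and parted Cre vehicle from floxed vehicle libraries.

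Xist, the RNA that silences 1 X chromosome in female cells, and 4 Y-linked genes split the libraries by sex in a way that crosses the groups. Xist stood at 0.478 to 0.888 CPM in floxed vehicle, 142 to 359 CPM in Cre vehicle and 0.047 to 0.207 CPM in Cre LPS libraries. In the floxed LPS group, replicates 3 and 6 had 283 and 282 CPM and replicate 5 had 0.205 CPM. The Y-linked sum was 111 to 146 CPM in floxed vehicle, 92.9 to 126 CPM in Cre LPS and 105 CPM in floxed LPS replicate 5, against at most 0.654 CPM in the other libraries. Genotype and sex pattern therefore coincided with vehicle, and with LPS all 3 Cre libraries had the male pattern against 1 of 3 floxed libraries.

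**Figure D1:**
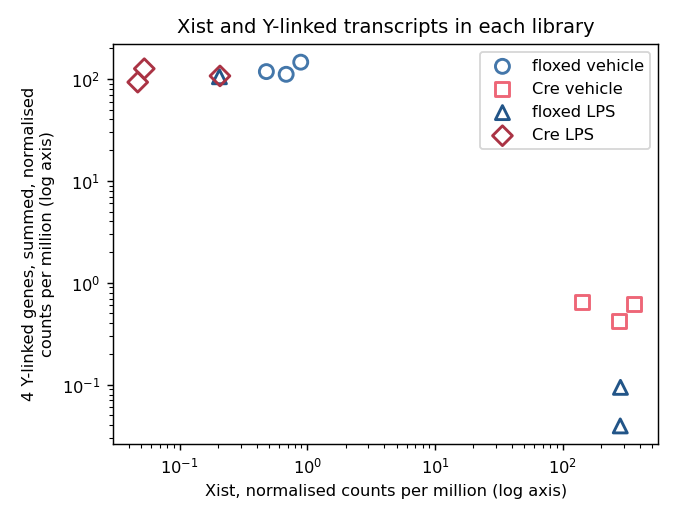
Xist (horizontal) against the sum of 4 Y-linked genes (vertical), in normalised CPM on log axes, with 1 point per library and 1 marker per group. The 3 Cre vehicle libraries and 2 of the 3 floxed LPS libraries lie at high Xist, from 142 to 359 CPM, and the other 7 below 1 CPM.

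Slc39a1 (ENSMUSG00000052310), the gene targeted in AT2 cells, did not differ between genotypes at the level of lung RNA. Its level was 79.2 ± 9.87 CPM in floxed vehicle and 76.4 ± 16.5 CPM in Cre vehicle lungs (SD, n = 3 each), and 135 ± 30.6 CPM in floxed LPS and 139 ± 16.7 CPM in Cre LPS lungs. The Cre to floxed ratio was 96.5% with vehicle (95% interval 72.6 to 128%, edgeR adjusted p = 0.853) and 103% with LPS (77.4 to 136%, adjusted p = 0.99). LPS raised Slc39a1 in floxed lungs (log2 fold change 0.77, SE 0.19, adjusted p = 0.00869) and in Cre lungs (0.86, SE 0.19, adjusted p = 0.00319). The rises did not differ by the interaction test (0.09, SE 0.27, adjusted p = 0.842). Counts were per gene and do not show single exons. Without floxed LPS replicate 5 the rise in floxed lungs was 0.56 and no longer passed, and with the sex covariate the rise in Cre lungs was 0.34 and did not pass.

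**Figure D2:**
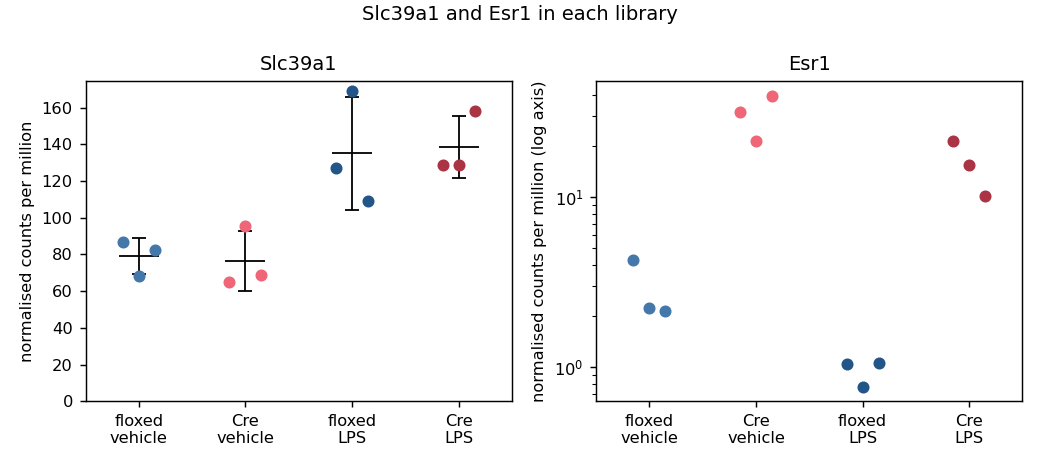
Slc39a1 (left, linear axis) and Esr1 (right, log axis) in normalised CPM, with 1 point per library. Bars on the left are the mean and SD of 3 libraries; Slc39a1 means with vehicle were 79.2 and 76.4 CPM, while Esr1 was at least 10.2 CPM in every Cre library and at most 4.3 CPM in every floxed library.

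With vehicle, the comparison sets Cre against floxed lungs without LPS. Genotype coincided with sex pattern here, so the differences cannot be credited to Cre alone. Most genes of fatty acid and sterol synthesis were lower in Cre lungs, as were erythroid and many heart muscle and mesothelium markers, while many inflammatory cytokines and most ribosomal proteins and dendritic cell markers were higher. These list calls were made with the preset correlation and were all lost with an estimated one. Of 17 lipid and sterol synthesis genes, 13 were lower and none higher (14 lower adjusted over the list alone; median log2 fold change -0.98). They included Fasn, fatty acid synthase (-1.83, SE 0.25), and Acaca, which makes malonyl-CoA (-1.51, SE 0.22), along with Hmgcr, the rate-limiting enzyme of cholesterol synthesis. Of 21 cytokine and chemokine genes, 12 were higher (12 adjusted over the list alone, median 1.96), among them the chemokines Ccl3 (3.35, SE 0.53) and Cxcl2 (2.62, SE 0.43) and the cytokine Tnf (2.24, SE 0.59). Levels were low: Ccl3 stood at 0.303 CPM in floxed vehicle and 3.1 CPM in Cre vehicle lungs, and Cxcl2 at 0.289 and 1.77 CPM. In floxed LPS lungs they stood at 158 and 133 CPM. In this list 3 members had 3 counts or fewer in a vehicle group. Ribosome genes were the most enriched pathway among higher genes, with 117 of 128 called (26.4 expected, adjusted p = 3.58e-64, hypergeometric test).

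Among cell markers, 8 of 12 dendritic cell genes were higher with vehicle (9 adjusted over the list alone), led by the antigen-presenting H2-Ab1 (1.19, SE 0.22) and H2-Eb1 (1.13, SE 0.23). Of 15 monocyte and macrophage genes, 7 were higher and 1 lower by either adjustment, with the complement gene C1qa at 1.45 (SE 0.24). Neutrophil markers moved the other way, with 7 of 15 lower and 1 higher by either adjustment, among them Camp (-2.31, SE 0.44) and Ngp (-2.56, SE 0.52). AT2 markers were lower for 7 of 18 genes and higher for 1, and AT1 markers lower for 7 of 14 and higher for 1, by either adjustment. Lower AT2 genes included Etv5, a transcription factor of AT2 identity (-1.36, SE 0.16), and Abca3, the lipid pump of lamellar bodies (-0.74, SE 0.17), whereas Sftpc stood at -0.12 (SE 0.37). In the tight junction and barrier list 9 of 21 were lower and 1 higher by either adjustment, including Ocln (-0.96, SE 0.12) and the sodium channel subunit Scnn1a (-0.95, SE 0.16).

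Some tissue markers from outside the alveoli also differed with vehicle. The adipose and skeletal muscle lists were not called by camera (adjusted p = 0.145 and 0.769). Their mean log2 levels, centred on the 12 libraries, varied within Cre vehicle. They were 1.951 and 1.304 in replicate 10, -0.2 and -0.259 in replicate 17, and -1.087 and -0.477 in replicate 19. In floxed vehicle libraries they were 0.935 to 3.488 and 0.669 to 1.916. All 9 erythroid genes were lower in Cre vehicle lungs by either adjustment (median log2 fold change -2.33), as were 6 of 11 heart muscle genes (10 adjusted over the list alone; median -3.09) and 5 of 8 mesothelium genes (6 adjusted over the list alone). The natriuretic peptide gene Nppa stood at 172 ± 261 CPM in floxed vehicle and 2.64 ± 4.34 CPM in Cre vehicle lungs (SD, n = 3 each), and its fold change did not pass with limma-voom, nor without floxed vehicle replicate 21, where it was -2.99. The share of mitochondrial counts was 4.03 to 9.89% in Cre vehicle and 2.48 to 4.25% in floxed vehicle libraries. Of 11 mitochondrial genome genes 3 were higher (2 adjusted over the list alone), with mt-Nd3, a complex I subunit, at 4.85 (SE 0.63), and camera did not call the list (adjusted p = 0.0611). Of 22 nuclear oxidative phosphorylation genes, 11 were higher and 5 lower (12 and 5 adjusted over the list alone).

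The largest rises with vehicle among named genes also held Saa3, an acute phase protein of macrophages and epithelium (5.31, SE 0.55), Mmp12, the macrophage elastase (3.80, SE 0.59), and the interferon-induced chemokine Cxcl9 (3.04, SE 0.84). Apoc2, a cofactor of lipoprotein lipase (3.13, SE 0.56), Syn3 (5.95, SE 0.85), Nhlrc4 (5.78, SE 1.55) and Derpc (3.65, SE 0.96) rose as well. In Cre vehicle lungs the SD exceeded the mean for Syn3 (212 ± 235 CPM) and Nhlrc4 (6.13 ± 6.28 CPM). Exosc6, a subunit of the RNA exosome, was at 2 counts over the 3 floxed vehicle libraries, and its ratio was 202 (95% counting interval 55.6 to 1680). Esr1, the oestrogen receptor alpha gene, stood at 30.9 ± 9.17 CPM in Cre vehicle and 2.9 ± 1.22 CPM in floxed vehicle lungs. Large falls were of Y-linked genes, with Ddx3y at least 1020-fold and Eif2s3y at least 535-fold lower, Uty at a ratio of 337 (115 to 1630) higher in floxed lungs and Kdm5d at -5.55 (SE 1.51). Others were the cardiac genes Tbx20 (-7.03, SE 1.10), Myom2 (-5.61, SE 1.17) and Lmod2 (-5.58, SE 1.04), with Slc17a7 (-6.13, SE 1.25) and Kcnj3 (-5.73, SE 1.19). Cxcl9 did not pass with limma-voom or without floxed vehicle replicate 22 or 23 or Cre vehicle replicate 17, and Derpc did not pass with the 6 libraries alone. With the sex covariate the Y-linked genes lost their calls or turned. Exosc6 lost its call with an unchanged fitted fold. Syn3 (5.08), Nhlrc4 (7.71), Derpc (3.59), Nppa (-9.02), Slc17a7 (-7.48) and Kcnj3 (-6.22) lost their calls too, with log2 fold changes of similar or larger size. DESeq2 gave Eif2s3y and Kdm5d no adjusted p.

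In all, 6849 of 17500 genes were called with vehicle by edgeR, 3585 higher and 3264 lower in Cre lungs, and camera called 12 of 45 lists. With library totals in place of TMM the count was 6908, with 2904 higher and 4004 lower, and the median of all genes moved from 0.03 to -0.08. No list kept its call with an estimated correlation; the lowest adjusted p = 0.825 with an estimated correlation was that of the lipid, cytokine, erythroid, neutrophil, dendritic cell, mesothelium, AT1 and barrier lists, while it was 0.857 for the heart muscle and monocyte lists and 0.971 for the AT2 and oxidative phosphorylation lists. The rotation test fry did not call the AT2 and heart muscle lists (adjusted p = 0.0583 each) and the oxidative phosphorylation list (0.066). Fold changes followed gene length: in 5 equal classes of length, the median was 0.63 for the shortest genes and -0.50 for the longest. With the length and GC trend taken out, 4508 genes were called, of which 3349 were among the 6849 and in the same direction, 86 ribosome genes were called higher with their median down from 0.96 to 0.50, and the oxidative phosphorylation list lost its call (adjusted p = 0.945). A covariate for sex left 2419 genes and ended the call of the barrier list. The stricter filter ended the calls of the AT2, barrier and oxidative phosphorylation lists. Single libraries ended list calls: floxed vehicle replicate 23 those of the AT2, AT1, barrier and oxidative phosphorylation lists, floxed vehicle replicate 22 those of the monocyte, barrier and oxidative phosphorylation lists, Cre vehicle replicate 17 those of the AT2, monocyte and barrier lists, replicate 10 that of oxidative phosphorylation and replicate 19 that of the barrier list, each when left out. The authors' table for this comparison lists 2601 genes; 2445 of them were tested here, all with the same sign, and 2337 were also called.

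**Figure D3:**
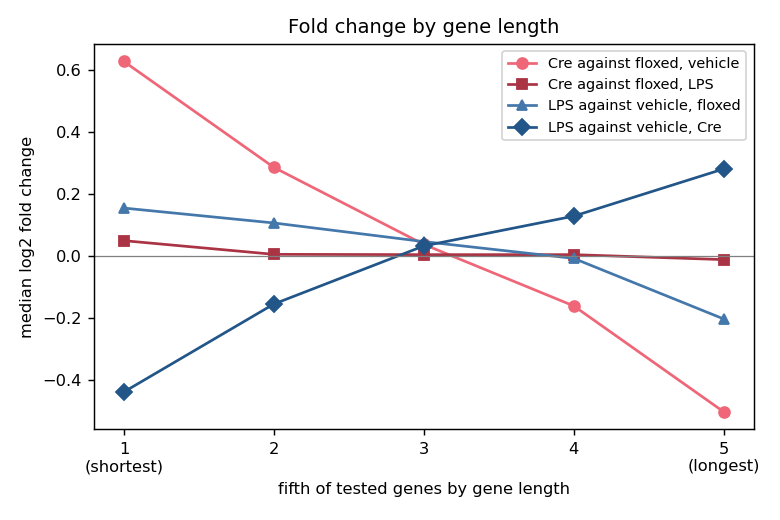
Median log2 fold change of the tested genes in 5 equal classes of gene length, from the shortest to the longest, with 1 line per comparison. The vehicle genotype comparison falls from 0.63 to -0.50, LPS in Cre lungs rises from -0.44 to 0.28, and the LPS genotype comparison stays between 0.05 and -0.01.

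With LPS, the comparison sets Cre against floxed lungs given endotoxin. Sex pattern was again uneven between these groups, so the differences cannot be credited to Cre alone. Interferon-induced genes and monocyte and macrophage markers were higher in Cre than in floxed LPS lungs, as were some genes of pyroptosis. Floxed LPS replicate 6 had the lowest mean log2 level of each list in its group, centred on the 12 libraries. It stood at -0.04 for interferon against 0.66 and 0.75 in replicates 3 and 5, and at 0.06 for monocytes against 0.42 and 0.77. With single libraries left out the interferon median log2 fold change was 1.07 to 1.32. All 20 interferon response genes were higher when adjusted over the list alone, and 9 over all genes, with a median fold change of 1.21 on the log2 scale. They included Ifit2, which binds viral RNA (2.09, SE 0.21), Rsad2, the antiviral enzyme viperin (1.84, SE 0.24), Isg15 (1.45, SE 0.22) and Irf7, a regulator of type I interferon (1.17, SE 0.18). Of 15 monocyte and macrophage genes, 5 were higher over all genes and 13 adjusted over the list alone (median 1.12), among them the Fc receptor genes Fcgr4 (1.69, SE 0.19) and Fcgr1 (1.47, SE 0.29) and the monocyte marker Ly6c2 (1.82, SE 0.29).

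In the pyroptosis and necroptosis list 1 of 14 genes was higher over all genes, Casp1, the inflammasome protease (1.17, SE 0.22), and 7 adjusted over the list alone (median 0.70). With an estimated correlation these 3 lists kept their calls, each with adjusted p = 0.0275. The other 16 of the 19 lists called by camera lost theirs. Among them, no club cell gene was called by either adjustment (median 1.34, adjusted p = 0.61 with an estimated correlation). No B cell gene was called either (-0.69, 0.27 with an estimated correlation), and the same held for smooth muscle genes (-0.54, 0.252 with an estimated correlation). Dendritic cell genes had 6 of 12 higher adjusted over the list alone and none over all genes (0.68, adjusted p = 0.27 with an estimated correlation), and cell cycle genes 5 of 20 (0.70, adjusted p = 0.568 with an estimated correlation). Of 21 cytokine and chemokine genes none was called over all genes and 2 were higher adjusted over the list alone (median 0.40, camera adjusted p = 0.0565). No AT2 marker, zinc importer or zinc exporter was called by either adjustment; Sftpc stood at -0.96 (SE 0.37), and the list medians were 0.07, -0.08 and -0.04.

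The named genes with LPS were all higher in Cre lungs. The largest was Ubd, a ubiquitin-like modifier induced by interferon gamma (4.04, SE 0.76), followed by Esr1 (4.02, SE 0.39), with 15.7 ± 5.62 CPM in Cre LPS and 0.956 ± 0.164 CPM in floxed LPS lungs (SD, n = 3 each). Ido1, which degrades tryptophan, stood at 3.11 (SE 0.55), the macrophage receptor Slamf8 at 2.24 (SE 0.43), Trim30c at 2.20 (SE 0.30) and Phf11a at 2.12 (SE 0.27). Ms4a4c (2.01, SE 0.31), Oas3, a sensor of double-stranded RNA (1.93, SE 0.27), and the protease inhibitor Serpina3g (1.91, SE 0.36) completed the set with Ifit2. Genes of the defence response to virus were the most enriched term, with 22 of 143 higher (0.961 expected, adjusted p = 1.34e-20).

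In all, edgeR called 113 genes with LPS, 112 higher and 1 lower; the lower one, Xist, was looked up after its value was seen. The count was 459 with DESeq2, 205 with limma-voom, 250 without a filter and 48 with library totals, which moved the median of all genes to -0.11. Single libraries moved it: it was 2 without floxed LPS replicate 3, 27 without floxed LPS replicate 6, 26, 18 and 58 without Cre LPS replicates 1, 3 and 4, 73, 75 and 49 without floxed vehicle replicates 21, 22 and 23, and 320 without Cre vehicle replicate 10. With sex as a covariate edgeR called 0 genes (686 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 23. The log2 fold changes of the named genes with that covariate ran from 1.11 (Serpina3g) to 4.34 (Esr1), none of them called by edgeR. Only Esr1 and Ifit2 among the named genes stayed called with each single library left out, and Ubd, Ido1, Slamf8 and Serpina3g were not called with library totals. Ubd was not called with the length and GC trend taken out (3.89, adjusted p = 0.0577), nor were Ido1 (3.09), Slamf8 (2.22) and Serpina3g (1.89) with only the 6 libraries compared. Against floxed LPS replicate 5 alone, the 1 male-pattern library, the interferon list kept a median log2 fold change of 1.07. With 1 library in that group, the p-values of that fit do not measure spread between floxed LPS animals. The authors' table lists 232 genes, all tested here with the same sign, and 82 of them were also called.

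**Figure D4:**
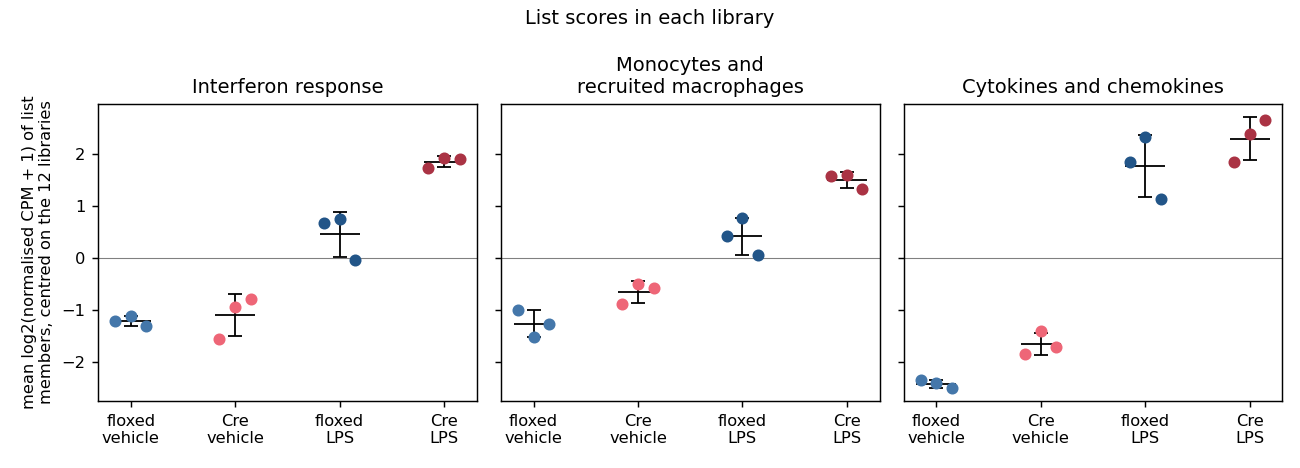
Mean log2 level of the members of 3 gene lists in each library, centred on the mean of the 12 libraries, with the mean and SD of each group of 3. Interferon scores lie between 1.73 and 1.93 in Cre LPS and between -0.04 and 0.75 in floxed LPS libraries.

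LPS in floxed mice shows the endotoxin response of control lungs. Cytokines, chemokines and acute phase proteins rose steeply, interferon genes and most NF-kB, antioxidant and unfolded protein response genes rose, and most club cell markers and over 0.5 of AT2 markers fell. All 21 cytokine and chemokine genes were higher by either adjustment (median 6.26), such as the neutrophil-attracting Cxcl2 (8.85, SE 0.37) and Cxcl3 (10.27, SE 0.45), Ccl3 (9.02, SE 0.49) and Il1b (5.02, SE 0.34). Of 16 acute phase and antimicrobial genes, 13 were higher and 1 lower by either adjustment (median 2.75), with Saa3 at 10.64 (SE 0.67) and Lcn2, an iron-sequestering protein, at 5.11 (SE 0.33); the lower one was Reg3g, an antibacterial lectin (-5.19, SE 1.70). All 20 interferon response genes were higher by either adjustment, as were 19 of 20 NF-kB and TLR genes (20 adjusted over the list alone), such as Tnfaip3, an inhibitor of NF-kB (3.01, SE 0.21). Of 15 antioxidant genes 12 were higher and 1 lower, and of 17 unfolded protein response genes 13 were higher, by either adjustment. Of these lists only the cytokine and acute phase lists kept their calls with an estimated correlation.

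Of 12 zinc importers 6 were higher (7 adjusted over the list alone) and none lower (adjusted p = 0.312 with an estimated correlation), led by Slc39a14 (2.35, SE 0.34) and Slc39a8 (1.29, SE 0.21), and the zinc-binding metallothioneins Mt2 (4.04, SE 0.38) and Mt1 (2.25, SE 0.35) rose. Of 7 zinc exporters 2 were higher by either adjustment, and camera did not call the list (adjusted p = 0.229). Of 12 club cell genes, 11 were lower by either adjustment, with the secretoglobin Scgb1a1 at -4.51 (SE 0.64). Of 18 AT2 genes, 10 were lower and 1 higher by either adjustment, with Sftpc at -1.97 (SE 0.38), Hc, complement C5, at -2.90 (SE 0.41) and the collectin Sftpd higher (1.09, SE 0.18). Of 15 neutrophil genes 11 were higher, such as Il1r2 (4.86, SE 0.45), and 2 lower, Camp and Ngp (3 lower adjusted over the list alone). Of 15 monocyte and macrophage genes 14 were higher (15 adjusted over the list alone).

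Erythroid, heart muscle and adipose markers, which were highest in the floxed vehicle group, fell with LPS in floxed lungs. These 3 list calls were lost with an estimated correlation (adjusted p = 0.217, 0.34 and 0.34). The counts were 9 of 9, 10 of 11 (11 adjusted over the list alone) and 8 of 9, and the medians were -2.36, -3.90 and -6.51. Named falls included the adipose genes Adipoq (-8.52, SE 1.66), Plin1 (-7.29, SE 1.38), Retn (-6.52, SE 1.69) and Car3 (-7.54, SE 1.47), and also Nppa (-8.98, SE 1.95) and Pck1, a gluconeogenic enzyme (-8.76, SE 1.36). In floxed vehicle lungs the SD exceeded the mean for Nppa (172 ± 261 CPM) and Adipoq (46.3 ± 52.6 CPM). Others were Bpifa1, an airway secretory protein (-8.21, SE 2.01), Slc5a8 (-7.09, SE 1.75), Cyp4a12b (at least 224-fold lower) and Atp6v1b1, a proton pump subunit, whose ratio was 268 (91.4 to 1300) higher with vehicle. Named rises included Gpr84, a receptor on activated myeloid cells, with a ratio of 635 (217 to 3080), Il6 with a ratio of 170 (57.8 to 827), Csf3, the granulocyte growth factor (7.48, SE 0.78), Orm2 (8.36, SE 0.46), Saa1 (8.33, SE 0.83) and Acod1, which makes itaconate (7.93, SE 0.77). Cyp4a12b, Nppa, Adipoq, Bpifa1, Car3, Plin1, Slc5a8 and Retn lost their calls with the sex covariate. They also lost them with floxed LPS replicate 5 as the only library of its group. Log2 fold changes with the covariate stayed large (Nppa -11.56, Adipoq -8.18, Bpifa1 -7.33, Car3 -6.92, Plin1 -6.73, Slc5a8 -5.84, Retn -5.80). Nppa, Adipoq and Retn were not called by limma-voom.

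In floxed lungs 6084 genes were called by edgeR, 3381 higher and 2703 lower with LPS, and camera called 32 of 45 lists. With an estimated correlation 2 lists kept their calls, the cytokine and the acute phase lists, each with adjusted p = 0.0339. It was 0.152 for the interferon list, 0.124 for the NF-kB and unfolded protein lists, 0.312 for the zinc importer, metallothionein and club cell lists, and 0.34 for the AT2 list. The adjusted p with an estimated correlation was 0.165 for the neutrophil list, 0.131 for the monocyte list and 0.152 for the antioxidant list. The floxed vehicle libraries had the male pattern and 2 of the 3 floxed LPS libraries the female pattern. The count was 3895 without floxed LPS replicate 5, 3133 with that library as the only one of its group and 3856 with the sex covariate.

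LPS in Cre mice raised most cytokine, neutrophil and acute phase genes and the interferon, NF-kB and monocyte genes. No list call was kept with an estimated correlation. Of 21 cytokine and chemokine genes 20 were higher by either adjustment (median 5.52), with Csf3 at a ratio of 380 (105 to 3140), Cxcl5 at 6.95 (SE 0.62) and Cxcl3 at 6.75 (SE 0.35). All 20 interferon genes were higher by either adjustment (median 2.98), with Rsad2 at 5.11 (SE 0.28) and the guanylate-binding protein gene Gbp2 at 5.64 (SE 0.62). All 20 NF-kB genes and all 15 monocyte and macrophage genes were higher by either adjustment. Of 15 neutrophil genes 12 were higher by either adjustment (median 3.17), such as the collagenase Mmp8 (4.93, SE 0.43) and the chemokine receptor Cxcr2 (4.14, SE 0.31). Of 12 zinc importers 8 were higher (9 adjusted over the list alone), led by Slc39a14 (2.47, SE 0.35) and Slc39a8 (2.44, SE 0.21).

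Capillary endothelium, B cell, mitochondrial genome and lipid synthesis list calls in Cre lungs were lost with an estimated correlation (adjusted p = 0.521, 0.451, 0.451 and 0.562). Of 16 capillary endothelium markers 10 were lower by either adjustment, such as Aplnr, the apelin receptor (-2.76, SE 0.41), and Gpihbp1, which anchors lipoprotein lipase (-1.51, SE 0.23). B cell markers were lower for 10 of 14 genes (11 adjusted over the list alone), with the light chain gene Igkc at -2.03 (SE 0.31). AT2 markers went both ways, with 4 of 18 higher and 7 lower by either adjustment and Sftpc at -2.81 (SE 0.40). Lipid and sterol synthesis genes were higher for 9 of 17 and lower for 1 by either adjustment, with Hmgcr at 1.23 (SE 0.16). Ribosome genes were lower for 73 of 128 (26.4 expected, adjusted p = 2.5e-16), with a median of -0.42; with the length and GC trend taken out 45 were lower and 7 higher, with a median of -0.18. In the mitochondrial genome 8 of 11 genes were lower by either adjustment, with mt-Nd3 at -4.66 (SE 0.63). Their share of counts was 4.03 to 9.89% in Cre vehicle and 1.9 to 2.56% in Cre LPS libraries. Further named rises were Gbp10 with a ratio of 1030 (353 to 5010), Orm2 (7.98, SE 0.45), Orm1 (7.02, SE 0.82), Trim30c, and the Y-linked Ddx3y (at least 979-fold), Eif2s3y (at least 459-fold) and Uty, with a ratio of 280 (95.4 to 1360).

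Named falls in Cre lungs were Exosc6 (at least 129-fold), Syn3 (-6.39, SE 0.88), Atp6v1b1 (-5.85, SE 1.18), Calml3 (-5.43, SE 1.22), Lypd2 (-4.71, SE 1.01) and Colq (-4.56, SE 0.42), with Kcnip4 (-4.60, SE 0.48), Ces2e (-4.53, SE 0.47) and Hpcal4 (-4.44, SE 0.38). In Cre vehicle lungs the SD exceeded the mean for Syn3 (212 ± 235 CPM), Atp6v1b1 (6.48 ± 8.6), Calml3 (16.8 ± 25.4) and Lypd2 (111 ± 163). In all, 8160 genes were called by edgeR, 4402 higher and 3758 lower, and camera called 23 of 45 lists. None kept its call with an estimated correlation: adjusted p = 0.0833 with an estimated correlation for the cytokine, interferon, neutrophil and acute phase lists, 0.108 for the NF-kB and monocyte lists and 0.403 for the zinc importers. The Cre vehicle libraries had the female pattern and the Cre LPS libraries the male pattern. The sex covariate left 1490 genes; the Y-linked genes lost their calls or turned, Exosc6 lost its call with an unchanged fitted fold, and calls were lost for Syn3 (-5.52), Lypd2 (-4.80), Kcnip4 (-3.67), Ces2e (-3.41), Calml3 (-3.02) and Atp6v1b1 (-2.29), and limma-voom did not call Calml3 and Lypd2. The lipid list was not called with the stricter filter, with the length and GC trend taken out (adjusted p = 0.0764) or without Cre vehicle replicate 19.

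**Figure D5:**
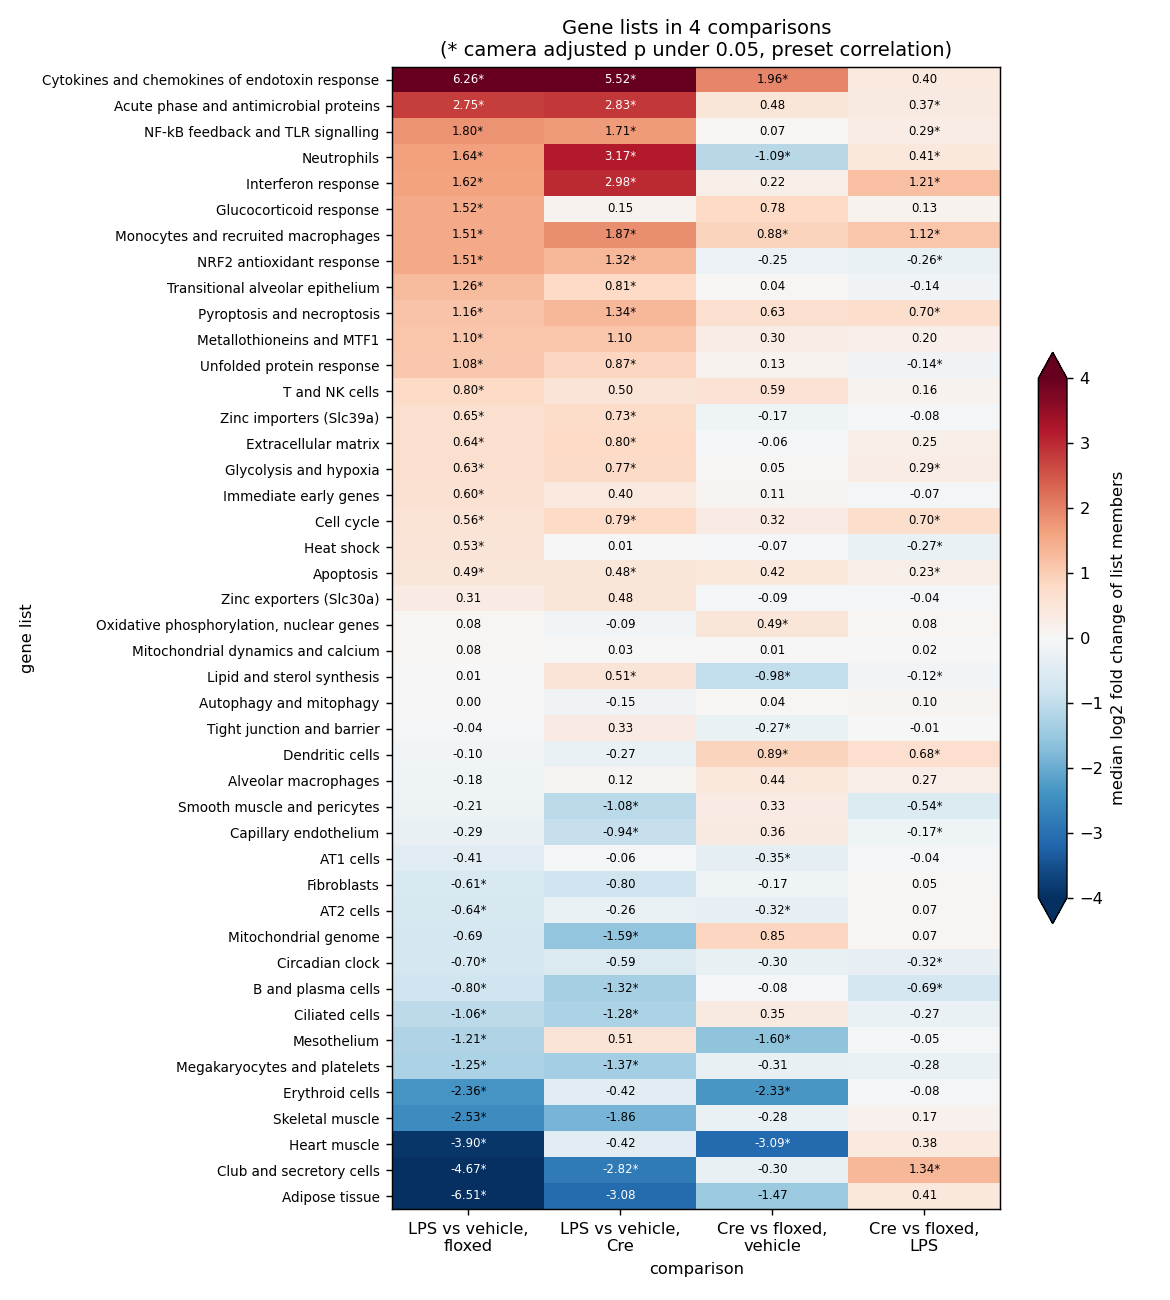
Median log2 fold change of the members of 44 gene lists (vertical) in 4 comparisons (horizontal), coloured from -4 to 4 with the value in each cell. An asterisk marks a camera adjusted p under 0.05 with the preset correlation; the cytokine list has the highest median in floxed lungs, 6.26, and the interferon list the highest in the LPS genotype comparison after the club cell list, 1.21.

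The interaction asks where the difference between LPS and vehicle lungs was unlike in Cre and floxed mice. A difference between the vehicle groups alone can bring this about. LPS raised some interferon and neutrophil genes more in Cre lungs and some cytokine genes less. These list calls were lost with an estimated correlation (adjusted p = 0.879, 0.879 and 0.936), and the sex covariate ended that of the interferon list (0.184) and left 1 gene with an interaction. The vehicle level of the cytokine list was higher in Cre lungs and that of the neutrophil list lower, while the interferon list was not called with vehicle (6 of 20 genes higher and 2 lower). Of 20 interferon genes 9 had a positive interaction (11 adjusted over the list alone; median 0.90), with Rsad2 at 3.39 (SE 0.35) and Ifit2 at 3.10 (SE 0.30). Those were the 2 genes lower in Cre lungs with vehicle, Rsad2 by a log2 fold change of -1.55 and Ifit2 of -1.02, which is part of their interaction. Of 15 neutrophil genes 8 had a positive interaction (11 adjusted over the list alone), with Mmp8 at 3.29 (SE 0.54). Of 21 cytokine genes 6 had a negative interaction (7 adjusted over the list alone, median -1.27), with Ccl3 at -3.64 (SE 0.62), Cxcl3 at -3.52 (SE 0.74) and Cxcl2 at -2.75 (SE 0.49). Ccl3 stood at 0.303 and 3.1 CPM in floxed and Cre vehicle lungs, and at 158 and 129 CPM in floxed and Cre LPS lungs. Of 17 lipid and sterol synthesis genes 7 had a positive interaction (8 adjusted over the list alone; median 0.77), with Fasn at 1.73 (SE 0.34). Ribosome genes had a negative interaction for 98 of 128 (13.5 expected, adjusted p = 1.86e-66), with a median of -0.90; with the length and GC trend taken out it was 53, with a median of -0.51.

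Other called interaction lists followed the tissue markers of the floxed vehicle group, with positive interactions for 6 of 9 erythroid genes (9 adjusted over the list alone), 3 of 11 heart muscle genes by either adjustment and 4 of 8 mesothelium genes (6 adjusted over the list alone). Capillary endothelium genes had a negative one for 5 of 16 by either adjustment. Named genes with a positive interaction were Ddx3y, Eif2s3y, Uty, Kdm5d, Nppa, Slc17a7, Tbx20, Kcnj3, Myom2 and Gbp10 (6.83, SE 1.55). Those with a negative one were Nhlrc4 (-7.02, SE 2.03), Syn3 (-5.97, SE 1.15), mt-Nd3 (-5.33, SE 0.83), Saa3 (-4.63, SE 0.68), Gpr84 (-4.38, SE 1.32), Ccl3, Cxcl3, Sap25 (-3.42, SE 0.64), Speer4c (-3.13, SE 0.91) and Tmem160 (-2.78, SE 0.36). In all, 3802 genes were called by edgeR, 1970 positive and 1832 negative, and camera called 8 lists, none of them with an estimated correlation (adjusted p = 0.879 for the interferon, neutrophil, lipid, erythroid and mesothelium lists, 0.936 for cytokines, 0.938 for heart muscle and 0.991 for capillary endothelium). The rotation test fry did not call the cytokine (adjusted p = 0.146), heart muscle (0.152) and capillary endothelium (0.278) lists. With the sex covariate edgeR called 1 gene (2892 at an unadjusted p under 0.05), limma-voom 1 and DESeq2 786, and with the length and GC trend taken out 1874 genes were called. Taking out that trend also ended the calls of 3 named genes. The sex covariate turned or ended the calls of the Y-linked genes and ended those of the other named genes, most of them with log2 fold changes about as large or larger, such as Myom2 (10.08), Tbx20 (7.68), Saa3 (-5.76), mt-Nd3 (-5.75) and Ccl3 (-4.80), and Sap25 with a smaller one (-2.61). It also ended the calls of the interferon, erythroid and capillary endothelium lists; the last was also lost with the stricter filter or without floxed vehicle replicate 22, Cre vehicle replicate 17 or floxed LPS replicate 6. With limma-voom Nppa, Slc17a7, Tbx20, Gbp10, Kcnj3, Nhlrc4, Syn3, Gpr84, Cxcl3 and Speer4c were not called, and Nppa, Slc17a7, Kcnj3, Nhlrc4, Gpr84 and Speer4c each lost their call with at least 1 single library left out.

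Averaged over vehicle and LPS, interferon, monocyte, dendritic cell and pyroptosis genes were mostly higher in Cre lungs and lipid synthesis genes mostly lower. These list calls, made with the preset correlation, were all lost with an estimated one. The counts were 16 of 20 interferon genes (17 adjusted over the list alone; median 0.80), 11 of 15 monocyte genes (13; median 0.98), 8 of 12 dendritic cell genes (9; median 0.76) and 9 of 14 pyroptosis genes (9; median 0.65). Of 17 lipid genes 11 were lower (14 adjusted over the list alone, median -0.56), and 11 of 21 cytokine genes were higher by either adjustment (median 1.23). For some lists the average came mainly from 1 treatment. With vehicle and with LPS, medians were -0.98 and -0.12 for lipid, 1.96 and 0.40 for cytokine, and 0.22 and 1.21 for interferon genes. Those of monocyte (0.88 and 1.12), dendritic cell (0.892 and 0.675) and pyroptosis genes (0.629 and 0.705) were closer. Named genes included Esr1 (3.71, SE 0.26), the interferon-induced chemokines Cxcl9 and Cxcl10 (2.42, SE 0.48), Saa3 (2.99, SE 0.35), Ido1 (2.08, SE 0.41), Acod1 (2.03, SE 0.45), Ubd, Apoc2, Dnase1l3 (1.97, SE 0.36) and the chemokine Ccl8 (1.92, SE 0.33). Lower named genes were Myocd, a smooth muscle coactivator (-1.79, SE 0.38), Sox6 (-1.33, SE 0.20), Egr3, Map3k19, Map3k13, Smad9, Homer2, Lrrn3, Peg10 and Magi3 (-1.06, SE 0.11).

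The average called 4501 genes with edgeR, 2591 higher and 1910 lower, and camera called 17 lists. No list kept its call with an estimated correlation (adjusted p = 0.454 for the interferon, dendritic cell and cytokine lists, 0.395 for the monocyte, pyroptosis and lipid lists). With library totals 4732 genes were called, 1645 higher and 3087 lower. The count was 2375 with the length and GC trend taken out, 645 with vehicle or LPS as an additive term, and 0 with 6 libraries against 6 regardless of treatment (3381 at an unadjusted p under 0.05; that design was run in edgeR only), which also ended the calls of the named genes. Most of their log2 fold changes stayed about as large there, such as Esr1 (3.59), Cxcl9 (2.96) and Magi3 (-1.09), while those of Saa3 (0.70), Acod1 (1.29) and Apoc2 (1.49) were smaller. The additive term ended the calls of Saa3 (2.80), Myocd (-1.75), Map3k19 (-1.30), Homer2 (-1.10) and Lrrn3 (-1.09), with log2 fold changes of similar size, and the length and GC correction ended that of Lrrn3 (-0.91).

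Of the 112 genes higher in Cre lungs with LPS, 42 were also called higher with vehicle, against 22.9 expected for independent calls, and 75.9% of the 112 had the same sign with vehicle. No gene was lower in both; across 17500 genes, which are not independent replicates, the correlation of fold changes was 0.042. This shared count was 1 without floxed LPS replicate 3 and 0 with the sex covariate. LPS effects in floxed and Cre lungs shared 1924 higher genes (850 expected) and 1122 lower genes (580 expected), with a correlation across genes of 0.584.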

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

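The tests of sex, of length and GC content as the whole cause, of monocytes and of the overall LPS response were chosen after the results were seen; the test of genes still called with length and GC content taken out, and the splits of the libraries, were set before. The interaction test called 3802 genes. Genotype called 6849 genes with vehicle and 113 with LPS. The log2 slope per doubling of gene length was 0.318 for the interaction and -0.348 for genotype with vehicle. The interaction count therefore largely followed the vehicle groups, where sex pattern and genotype coincided, and does not by itself show a different response to LPS. Lists whose interaction camera called with the preset correlation had median log2 differences of 0.90 (interferon), 1.604 (neutrophils), 0.77 (lipid and sterol synthesis), 2.09 (erythroid), 3.67 (heart muscle), 1.66 (mesothelium), -1.27 (cytokines) and -0.72 (capillary endothelium), and all 8 lost their call with an estimated correlation (adjusted p from 0.879 to 0.991). Of the genes named in a genotype comparison, 19 had an interaction, which follows in part from their choice by a large genotype difference. With the sex covariate edgeR called 1 gene for the interaction.

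Loci without a gene name were outside the comparisons. Of 450 with enough counts, edgeR called 110 for genotype with vehicle, 2 for genotype with LPS, 90 for LPS in floxed lungs, 274 for LPS in Cre lungs, 60 for the interaction and 44 for the average.

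The vehicle difference, with short genes higher and long genes lower in Cre lungs, was weighed against bias and sex. With the length and GC trend taken out of each library, 3349 of the 6849 genes were still called the same way, just under 0.5 of them, so a bias in the libraries stays open for the rest; the correction would also take out a biological difference that follows gene length. A smooth trend on length and GC content did not account for all of the difference, since 4508 genes were called after that correction. Library bias of another form was not tested. A sex difference of similar size with and without LPS, as the only cause, needed a negative slope of the LPS comparison on the vehicle comparison. Over 6646 genes off X and Y the slope was 0.031 (0.002 to 0.061 with single libraries left out), and Xist with 4 Y-linked genes gave -0.337. These values argue against sex as the only cause. The slope cannot exclude a sex difference offset by a genotype effect, since sex pattern and genotype were confounded. It also does not allow for the length trend, seen mainly with vehicle. A sex difference only without LPS or mixed with a genotype effect, tissue carried over at dissection and an effect of the knockout stay open. They could not be separated in this design.

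Interferon genes were higher in Cre LPS than in floxed LPS lungs. A rise of the whole LPS response as large as that of the interferon genes was not seen. The cytokine and chemokine list had a median of 0.40 against 1.21 for the interferon list, and lay below it by at least 0.54 with each library left out. Against the 1 male-pattern floxed LPS library the cytokine median was -0.009, a value that rests on 1 library in that group. A smaller rise of the whole response over all libraries stays open. The NF-kB, acute phase and neutrophil lists had medians of 0.295, 0.371 and 0.413, with camera calls that were lost with an estimated correlation (adjusted p = 0.575, 0.402 and 0.575). More monocytes and macrophages in the Cre LPS lungs may account for the interferon difference: their markers had a median of 1.12, and 0.746 against the 1 male-pattern floxed LPS library, and lung tissue holds such cells in every group. The marker list cannot tell more cells from higher levels per cell. The alveolar macrophage list had a median of 0.27, with no member called. Sex cannot be told apart with 1 male-pattern floxed LPS library, against which the interferon median was 1.07. An effect of the knockout stays open and untested apart from these.

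Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each of the 4 comparisons 1 split, the real one, gave as many called genes, and the highest other split had 0 by edgeR, the tool used for splits. Real and highest other counts at an unadjusted p under 0.05 were 8393 and 2282 for genotype with vehicle, 1597 and 1538 for genotype with LPS, 7975 and 770 for LPS in floxed lungs, and 9492 and 1658 for LPS in Cre lungs. For the interaction, 4 of 100 drawn splits of the genotype labels gave as many as the real 3802 genes (highest other 5001), and for the average 2 of 100 gave as many as 4501 (highest other 5001). Both shares are under 0.05, but each split as large kept the 2 vehicle groups whole, as 14 of the 100 did, and the highest among splits that mixed them was 0 by edgeR. Both counts therefore followed the vehicle comparison, for which the splits are too few.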

How the results depend on the processing

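The labels give no batch, sex or litter, and sex pattern coincided with genotype with vehicle. Where an alternative changed a result, the cause was not tested. No paired analysis was possible because floxed LPS and Cre LPS share only 1 replicate number, 3, and the vehicle groups share none. The fit without 2 floxed LPS libraries leaves 1, which is assumed to vary like the other groups. Counts of called genes, by edgeR unless named, were 6849 (genotype with vehicle), 113 (genotype with LPS), 6084 (LPS in floxed lungs), 8160 (LPS in Cre lungs), 3802 (interaction) and 4501 (average).

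With the sex covariate they were 2419, 0 (686 at an unadjusted p under 0.05), 3856, 1490, 1 (2892 unadjusted) and 4248. For genotype with LPS, DESeq2 with the covariate gave 23 and limma-voom 0, and for the interaction they gave 786 and 1. The covariate moved Slc39a1 with LPS in Cre lungs to 0.34 and turned Uty with vehicle (2.68), with LPS in Cre lungs (-2.93) and in the interaction (-2.30), and Kdm5d with vehicle (3.88) and in the interaction (-4.01). It turned the glycolysis list with LPS (adjusted p = 0.847), as did the male-pattern floxed LPS library alone (0.824). With that library alone, 0 genes were called for genotype with LPS (663 unadjusted; other tools were not run) and 3133 for LPS in floxed lungs. With the length and GC trend taken out, counts were 4508 for genotype with vehicle, 1874 for the interaction and 2375 for the average, and the oxidative phosphorylation list turned with vehicle (adjusted p = 0.945). A log2 fold change of at least 1 left 2558 for genotype with vehicle, 2852 and 3925 for LPS in floxed and Cre lungs, 1858 for the interaction and 574 for the average. For genotype with LPS, library totals gave 48, no filter 250, DESeq2 459 and limma-voom 205. For the average, an additive model gave 645, and 6 against 6 gave 0 (3381 unadjusted; edgeR only).

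Camera called 12, 19, 32, 23, 8 and 17 lists in the 6 comparisons, and with an estimated correlation 0, 3, 2, 0, 0 and 0. For genotype with LPS fry called 3. No filter gave 19 lists for genotype with vehicle and 18 for the interaction, and length and GC correction 17 for the interaction. Genes changed alike by genotype with vehicle and LPS, 42, became 17 with library totals, 94 without a filter, 0 with the sex covariate, 161 with DESeq2, 65 with limma-voom and 25 with length and GC correction; genes changed alike by LPS, 3046, became 521 with the sex covariate.

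With single libraries left out, counts ran from 5308 to 7695 (genotype with vehicle), 2 without floxed LPS replicate 3 to 320 without Cre vehicle replicate 10 (genotype with LPS), 3895 without floxed LPS replicate 5 to 7650 (LPS in floxed lungs), 6787 to 8064 (LPS in Cre lungs), 2543 to 4913 (interaction) and 3150 to 5826 (average). Lists ran from 9 to 21 with vehicle and 8 to 16 in the interaction, genes alike by genotype from 1 to 131 and by LPS from 2140 to 3319, and Slc39a1 with LPS in floxed lungs from 0.56 without floxed LPS replicate 5 to 0.88. Over all alternatives, including those above, called lists were the same in 2014 cases, weaker in 254 and reversed in 3, and named genes the same in 2110, weaker in 213 and reversed in 5. Most of these cases left out 1 library, often one outside the comparison, so the totals do not measure how firm the calls were. The estimated correlation by itself made most called lists weaker.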

Other observations

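In Cre vehicle lungs the zinc-binding metallothioneins Mt1 and Mt2 were higher than in floxed vehicle lungs, by log2 fold changes of 1.19 and 1.49, and the zinc-sensing factor Mtf1 was lower (-0.58). The list of these 4 genes, with 2 higher and 1 lower, was not called (median 0.30, camera adjusted p = 0.829). Zinc importers went both ways there, with 1 of 12 higher and 4 lower, and camera did not call the list (adjusted p = 0.436). Among zinc exporters 2 of 7 were lower (adjusted p = 0.493).

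LPS raised genes of the proteasome in floxed lungs, with 40 of 44 higher (8.83 expected, adjusted p = 2.01e-20, hypergeometric test). Fold changes in that comparison followed gene length, with a median of 0.154 for the shortest of 5 classes and -0.203 for the longest. The proteasome count was not repeated with that trend taken out. Ribosome genes were higher there for 76 of 128 and lower for 1. With the length and GC trend taken out 57 were higher and 2 lower. Smooth muscle and pericyte markers were lower with LPS in Cre lungs for 7 of 12 genes, and transitional alveolar epithelium markers were higher for 7 of 12 in Cre and 8 of 12 in floxed lungs. With an estimated correlation the adjusted p was 0.403 for the smooth muscle list and 0.483 and 0.211 for the transitional lists.

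Both tests of Esr1 were chosen after its level was seen. Esr1 was higher in all 6 Cre libraries than in any floxed library. Sex of the animals was excluded, since Esr1 was higher by 4.02 on the log2 scale in Cre LPS libraries, all of male pattern, than in floxed LPS libraries, 2 of 3 of which had the female pattern. Reads of the CreERT2 transgene, which holds only part of the oestrogen receptor, may have been counted at Esr1: the length implied by the deposited counts and TPM was 1244 to 1499 bases in Cre and 4910 to 7093 in floxed libraries, a log2 ratio of -2.03 with LPS and -2.29 with vehicle, with a lower ratio in 0 of 212 and 1 of 1995 listed genes. Coverage of single exons would be needed to test this, and a rise of Esr1 itself stays open.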
